A study of Mus musculus with 4 samples.

How the data were processed

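RNA was extracted from 4 cultures of the C2C12 line, labelled with biotin and hybridised to Affymetrix mouse whole-transcript arrays, 1 array per group, per the labels' protocols. The groups, taken from the sample labels, were proliferating and differentiating cells with a control siRNA and proliferating and differentiating cells with an siRNA against MUNC. The labels do not say that the 2 states or the 2 siRNAs were run on shared days, and scan dates were not used here.

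The deposited table holds 1 value per transcript cluster and array, made with Affymetrix Expression Console per the submitters' processing notes. Its version, the background correction, the summarization, the normalization and the genome build are not given in the sources used here. The deposited values were taken to be on a log2 scale because they run from 2.56 to 14.3, above the 11.1 that the natural logarithm of a 16-bit scanner value can reach and below its binary limit of 16. The sorted values of the 4 columns differed from their common mean by a median of 0.0186 and at most 0.142, so the authors' normalization left nearly equal distributions. Every fold below assumes this scale. Scanner files, detection calls and depth were not used here, so signal over background is known only from the level of a value.

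Clusters were named through a table that pairs them with the platform's annotation. Of 23332 clusters, 14996 had 1 gene symbol, 1019 had several genes and 7317 had none in that table, which leaves them unnamed here. Entrez identifiers of 14941 of the single-gene clusters were found in a RefSeq gene table (assembly GRCm38.p6), used only for names and neighbouring genes, and 55 were not. No symbol needed updating. The clusters gave 14860 genes, 135 of them with more than 1 cluster, each represented by the cluster with the highest mean over the 4 arrays. Where 51 genes had 2 clusters above the filter, their differences correlated across genes at 0.864 for differentiation in control cells and 0.838 in siMUNC cells, and at 0.658 and 0.792 for the knockdown in proliferating and differentiating cells. Several myosin heavy chain genes, Myh3 among them, lie in clusters with several genes or have no cluster of their own and were not analysed here.

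The deposited values were used as they stand. A comparison is the log2 difference between 2 arrays, and the difference of differentiation effects takes all 4. With 1 array per group there is no spread within a group to test these differences against. Genes were therefore counted past an absolute log2 difference of 1 (2-fold) among expressed genes. A model of siRNA and state that leaves out the difference of effects was not fitted. An expressed gene had its higher value among the arrays compared at or above the median of gene means over the 4 arrays (8.50). The genes left out as dim numbered 7004 for differentiation in control cells, 206 of them past 2-fold, and 7225 for the knockdown in differentiating cells, 76 of them past 2-fold.

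Before the data were examined, 22 gene lists and 7 lists of markers of other cell types and states were fixed. The gene lists cover myogenic transcription factors, thick filament, thin filament and Z-disc, excitation-contraction coupling, neuromuscular junction, myoblast fusion, muscle energy metabolism, mitotic genes, DNA replication, cell cycle exit, inhibitors of myogenesis and Notch, serum and immediate early genes, extracellular matrix, interferon response, inflammatory cytokines, p53 targets, endoplasmic reticulum stress, cholesterol synthesis, oxidative phosphorylation, ribosome biogenesis, housekeeping and long noncoding RNAs. The marker lists cover osteoblast, adipocyte, chondrocyte, smooth muscle and myofibroblast, fibroblast, macrophage, and reserve and satellite cells. All measured members were kept, so list counts and medians include dim genes. Coverage was lowest for long noncoding RNAs (3 of 11 members) and thick filament (8 of 17). The median of a list was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and called outside when beyond their central 95%. This placing describes these arrays and is not a test of the conditions. With 145 placings some fall outside by chance. Of the 29 lists, 12 and 16 were outside for differentiation in control and siMUNC cells. For the knockdown 15 were outside in proliferating and 15 in differentiating cells, and 14 for the difference of effects. Members of a list may vary together, which random lists do not copy, so a place outside was common.

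Genes higher or lower on differentiation were picked by the mean of the differences in control and siMUNC cells, at least 1 or at most -1, rather than from the control arrays alone, which would share the differentiating control array with the knockdown difference.

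The named genes were chosen by a rule fixed before the data were examined: the 12 highest and 12 lowest expressed genes of each comparison, leaving out model names, olfactory and vomeronasal receptors and microRNA or snoRNA genes; up to 4 members of each list with the largest absolute difference; Myod1, Myog, Myh3, Mymk, Ckm, Cdkn1a, Mki67, any cluster of MUNC and the genes next to Myod1; and the 6 expressed genes with the largest difference among those past 0.58 (1.5-fold) in opposite directions in the 2 knockdown comparisons. Genes left out for their names numbered 5, 2, 1, 2 and 2 past 2-fold in the 5 comparisons. Other list members are named as examples after their values were seen.

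The steps were tested on simulated data for the knockdown in differentiating cells, with 200 of 14860 genes changed and a noise SD of 0.164 per array. Of genes changed by a log2 of -2, 1.5 or 2, 100% were called past 2-fold in the right direction, and of those changed by -1.5, 98%. Of the unchanged genes 0 were called. Of unchanged lists 7.67% fell outside the central 95%, and 100% of lists with 9 of 15 members lowered were placed below it. The simulated noise was normal, equal at all levels and independent between genes. Changed genes were drawn only from brighter genes, which pass the filter, and changed by far more than the noise. Their near-complete calling was thus largely fixed in advance, and changes in dim genes were not simulated. These rates therefore check the steps and do not carry over as error rates of the real arrays.

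Alternatives fixed beforehand were quantile normalization, centring each array on its median and cyclic loess (limma 3.58.1); no filter on dim genes and a filter at the 75th percentile; an offset of 50 on the linear scale and a floor at the 25th percentile; the mean of a gene's clusters; thresholds of 1.5-fold and 3-fold; and a threshold of 3 running SDs (1.4826 times the median absolute deviation over 500 genes nearest in expression). Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.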

Results

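Gene expression was measured in C2C12 cells, a mouse myoblast line that divides in serum-rich medium and fuses into contractile myotubes when serum is lowered. Cells had received either a control siRNA or an siRNA against MUNC (siMUNC), a long noncoding RNA transcribed upstream of Myod1, the gene of the muscle-determining transcription factor MyoD. Each culture was taken either while proliferating in 10% fetal bovine serum or 3 days after a change to 2% horse serum, made at 80% confluence. This gave 4 groups with 1 array each, so there are no replicates. No difference below has a replicate check, no p-value was computed, and the number of arrays limits the precision. Each array gave 23332 transcript-cluster values on a log2 scale, with medians of 8.03 (control, proliferating), 7.96 (siMUNC, proliferating), 7.99 (control, differentiating) and 8.01 (siMUNC, differentiating). Across all clusters the lowest correlation between arrays was that of proliferating with differentiating control cells (r = 0.964) and the highest that of the control and siMUNC proliferating cells (r = 0.988).

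The targeted RNA itself was not analysed here. The gene table lists MUNC as Gm45923, between Otog and Myod1, and 0 of the named clusters were paired with it. The depth of the knockdown in these cells is therefore unknown, and the siMUNC groups are used as labelled. Of the neighbouring genes, Myod1 (transcript cluster 6960454) read 11.46 in control and 10.96 in siMUNC proliferating cells, and 11.75 and 10.70 in the respective differentiating cells. It was thus 1.42-fold lower with siMUNC before and 2.06-fold lower after the change of medium. The other neighbours, Otog (7.63 and 7.35 in control and siMUNC differentiating cells), Kcnc1 (7.81 and 7.70) and Sergef (8.10 and 8.24), read below the level counted as expressed there, so their small differences decide nothing.

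The first comparison asks which genes differ between differentiating and proliferating cells treated with the control siRNA. Genes of the contractile apparatus and of calcium handling were among those higher in differentiating cells by the widest margins. Myoz2, a Z-disc protein, was 88.1-fold higher, and Casq2, a calcium-binding protein of the sarcoplasmic reticulum, 75.8-fold higher. Such folds rest on dim values in proliferating cells (5.24 for Myoz2 and 6.29 for Casq2) and depend on the background: an offset of 50 took the log2 differences from 6.46 to 5.27 and from 6.24 to 5.54. The troponin subunits Tnnc2, Tnni1 and Tnnc1 were 49.3-fold, 36.1-fold and 32.4-fold higher. Myog, which encodes the differentiation factor myogenin, was 13.7-fold higher, and Mymk, which encodes the fusion protein myomaker, 14.4-fold higher, whereas Myod1 was 1.22-fold higher. Genes of DNA replication and mitosis were lower, among them Tk1 (thymidine kinase, 9.05-fold), Ccne2 (cyclin E2, 8.57-fold), Ttk (7.79-fold), Aurka (7.41-fold) and the proliferation marker Mki67 (7.10-fold).

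Taken by fixed gene list, 8 of 8 thick filament genes were past 2-fold higher (median log2 difference 4.67), as were 16 of 20 thin filament and Z-disc genes (2.57), 16 of 19 excitation-contraction coupling genes (2.35), 9 of 14 muscle energy metabolism genes (2.18) and 5 of 9 neuromuscular junction genes (1.14). Lists keep members that are dim on every array, such as Myl2 of the thick filament (4.22 in proliferating and 5.77 in differentiating control cells). Examples are Myl1 (5.17), Acta1 (4.61), Cacna1s, the voltage sensor of the muscle calcium channel (5.13), Pygm, muscle glycogen phosphorylase (4.41), and Chrng, the fetal acetylcholine receptor subunit (3.51). Of 11 myogenic transcription factors, Myog, Smyd1 (2.91) and Mef2c (2.70) were past 2-fold higher. The mitotic list had 19 of 20 members past 2-fold lower (median -2.42) and the DNA replication list 24 of 25 (-2.03). Of the 10 cell cycle exit genes, Gadd45a (2.38), Cdkn1c (1.63) and Rb1 (1.40) were past 2-fold higher, while Cdkn1a, an inhibitor of cyclin-dependent kinases, was 1.92-fold higher. The 15 ribosome biogenesis genes were all lower (median -0.45), with Nop58 past 2-fold (-1.04), a margin that 2 of 3 other scalings put below 2-fold. Housekeeping genes stood just below their random range (-0.40, with Rplp0 at -1.28), and quantile normalization took them back inside. The extracellular matrix list held members in both directions, with Lum (4.87), Dcn (2.21), Col6a2 (2.03) and Col6a1 (1.59) past 2-fold higher and Tnc (-1.74) past 2-fold lower. Among serum and immediate early genes, Ccn2 (-1.78), Fosl1 (-1.60) and Myc (-1.02) were past 2-fold lower, Myc by a margin that all 3 other scalings put below 2-fold. The Notch and inhibitor list had a median of -0.05, inside its random range, with 8 of 17 members above 0 and 9 below. Its members Id2 (-1.51), Id1 (-1.39) and Id3 (-1.18), which block myogenic basic helix-loop-helix factors, were past 2-fold lower, while Mstn (myostatin) read past 2-fold higher (1.08) from low levels (5.54 and 6.62), which cyclic loess put at 0.98 and an offset of 50 at 0.62.

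In total 409 of 7856 expressed genes were past 2-fold higher and 517 past 2-fold lower in differentiating control cells, 11.8% together. Of these, 150 and 162 were past 4-fold. The 12 highest also held Tm6sf1 (60.6-fold), Smpx (52.7-fold), Cap2 (33.2-fold), Casq1 (31.1-fold) and Mylpf (30.4-fold). The lowest, beside Tk1, were Tmprss11f (18.0-fold), Ccdc73 (log2 difference -3.90), Havcr2 (10.1-fold), Ercc6l (9.86-fold), Hhip (9.62-fold) and Cenph (8.70-fold). Among 7 lists of markers of other cell types and states, the fibroblast list stood above its matched random lists (median 0.60, with Dpt at 3.72). The macrophage list, a type this line should lack, had a median of 0.11, inside the random range. Medians inside that range were also seen for osteoblast (0.30), adipocyte (0.24), chondrocyte (0.26), smooth muscle and myofibroblast (0.26) and reserve and satellite cell markers (0.17).

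**Figure D1:**
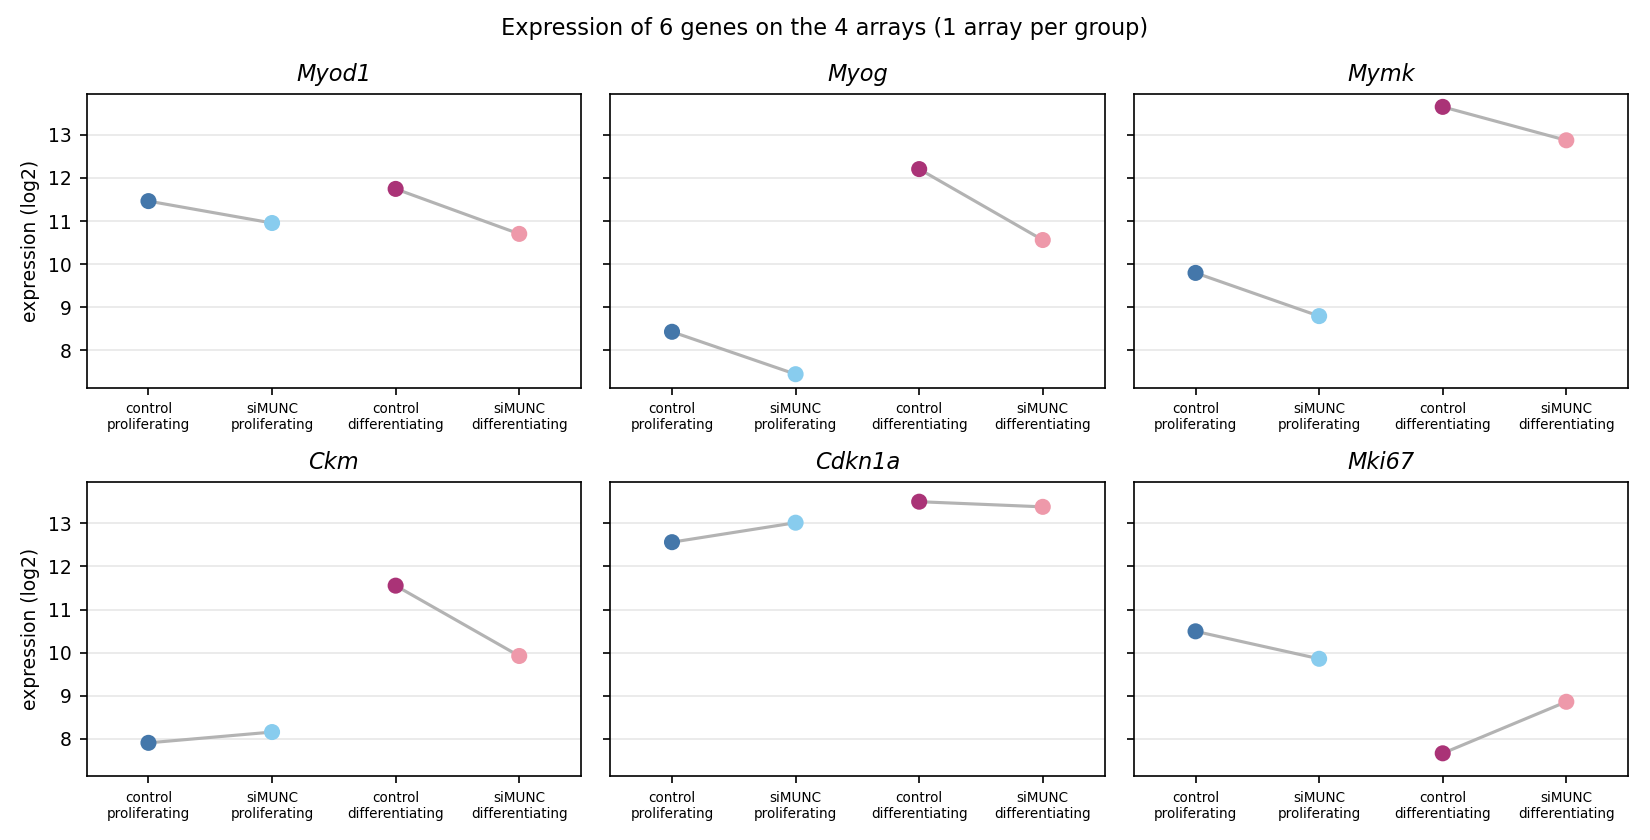
Expression of 6 genes fixed before the data were examined, on the log2 scale (vertical axis), on the 1 array of each of the 4 groups (horizontal axis); each point is 1 array and the grey lines join the control and siMUNC arrays of a state. Myog read 12.21 in control and 10.56 in siMUNC differentiating cells, and Mki67 read 7.67 and 8.86.

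The same comparison in siMUNC cells asks how far these cells take the same path. Most of the highest were again muscle genes: Myl1, a myosin light chain, came first (41.7-fold higher in differentiating cells), with Casq2 (25.5-fold), Mylpf (23.4-fold), Tnnt3 (23.4-fold) and Atp2a1, the calcium pump of the sarcoplasmic reticulum (22.2-fold). Dpt, a member of the fibroblast list, was 26.0-fold higher, next after Myl1. The folds of Myl1 and Dpt rest on dim values in siMUNC proliferating cells (6.97 and 6.98) and depend on the background. Mymk was 16.9-fold higher, Myog 8.64-fold and the muscle creatine kinase Ckm 3.40-fold, against 12.5-fold for Ckm in control cells. The lowest genes were Adgrg3 (4.97-fold), Slco4a1 (4.32-fold), Tinagl1 (4.26-fold) and Id3 (3.68-fold), and Mki67 was 2.00-fold lower.

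Of the fixed lists, 6 of 8 thick filament genes were past 2-fold higher (median 2.63), 13 of 20 thin filament and Z-disc genes (1.34), 10 of 19 excitation-contraction coupling genes (1.21), 7 of 14 muscle energy metabolism genes (0.92) and 2 of 9 neuromuscular junction genes (0.40). The 4 myogenic transcription factors past 2-fold higher were Myog (3.11), Smyd1 (2.64), Mef2c (1.64) and Myf6 (1.45). Myf6 read below the level counted as expressed on both siMUNC arrays (7.01 and 8.46). Of the mitotic list 8 of 20 were past 2-fold lower (median -0.97), and of the DNA replication list 7 of 25 (-0.83). Expressed genes past 2-fold numbered 224 higher and 103 lower among 7672, with 57 and 3 past 4-fold.

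The sets from control and siMUNC cells, which share no array, overlapped in direction. Of 7560 genes expressed in both comparisons, 173 were past 2-fold higher in both, against 8.74 for independent lists, and 99 lower, against 6.52. Past 2-fold higher were 303 of the 7560 in control and 218 in siMUNC cells, and past 2-fold lower 483 and 102. The filter thus kept 303 of the 409 genes higher in control cells and 483 of the 517 lower. The others, such as Lbp (6.90 and 7.01), were dim on both siMUNC arrays, so the overlap and correlation leave them out. None of the 7560 was past 2-fold in opposite directions. Across these genes, which are not independent replicates, the differences had a Pearson correlation of 0.863.

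**Figure D2:**
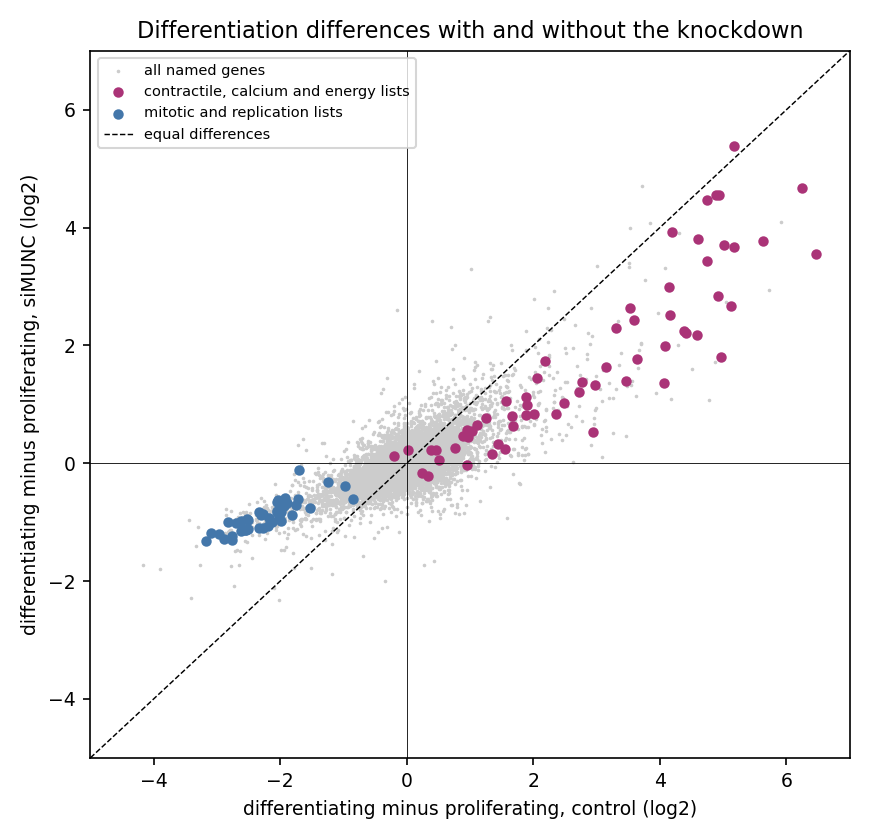
Difference between differentiating and proliferating cells on the log2 scale for each named gene, in control cells (horizontal axis) and siMUNC cells (vertical axis); coloured points are members of the muscle lists and of the mitotic and replication lists, and the dashed line marks equal differences. Most coloured points lie between the dashed line and 0 on the vertical axis, such as Casq1 at 4.96 and 1.81, while Myl1 lies at 5.17 and 5.38.

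The comparison of the siRNAs in proliferating cells asks what the knockdown does before differentiation is induced. Differences were small: 7 of 7564 expressed genes were past 2-fold higher, 23 past 2-fold lower, and 0 past 4-fold. Of 7296 dim genes 57 were past 2-fold, a larger share (0.781%) than among expressed genes (0.397%). The single genes named next are therefore not shown to stand above the noise of 2 arrays. The lowest with siMUNC were the chemokine Cxcl13 (3.76-fold), the membrane glycoprotein Cd200 (2.78-fold), carbonic anhydrase 2 (Car2, 2.77-fold), C1qtnf3 (2.63-fold), Oscp1 (2.55-fold), the potassium channel Kcnj2 (2.55-fold) and Bdkrb1 (2.33-fold). The highest were Tagln, an actin-binding protein of smooth muscle (2.90-fold), the thiamine transporter Slc19a2 (2.48-fold), the p53 target Trp53inp1 (2.29-fold), Tmem150a (2.25-fold), Txnip (2.20-fold), Rbm18 (2.15-fold) and Il33 (2.02-fold).

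In proliferating cells, 9 of 11 myogenic transcription factors were below 0 with siMUNC (median -0.31, below the central 95% of matched random lists), led by Mef2c (-0.99), Myog (-0.98), Smyd1 (-0.85) and Myf6 (-0.74), though none was past 2-fold. Mef2c (8.23 and 7.24 in control and siMUNC cells), Myog (8.43 and 7.45) and Myf6 (7.75 and 7.01) read below the level counted as expressed. Myf5 was higher (0.43). Myl1 (2.07-fold) and Mymk (2.00-fold) were past 2-fold lower, but centring the arrays put Myl1 at -0.98 on the log2 scale, and all 3 other scalings put Mymk within 2-fold (-0.99 to -0.93). Myl1 was also dim in both (8.02 in control and 6.97 in siMUNC cells). Other muscle lists had medians of -0.13 for thick filament, -0.11 for thin filament and Z-disc (just below its random range, and back inside under cyclic loess or an offset of 50), -0.06 for excitation-contraction coupling and -0.02 for muscle energy metabolism, while myoblast fusion was at -0.01 and neuromuscular junction at 0.03, both inside their random ranges. The sign of excitation-contraction coupling and of muscle energy metabolism turned when the arrays were centred, and that of muscle energy metabolism also under quantile normalization. With dim values set to a floor at the 25th percentile of each array, thick filament turned to 0.04 and muscle energy metabolism to 0.02. DNA replication genes were lower in 25 of 25 cases (median -0.40) and mitotic genes in 19 of 20 (-0.30), with Tk1 (2.00-fold lower), Cdc6 (-0.68), Mki67 (-0.64) and Mcm4 (-0.63) farthest.

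Cholesterol synthesis genes were lower in 15 of 15 cases (median -0.38), with Msmo1 (-0.72) and Cyp51 (-0.65) farthest. Higher as lists were p53 targets (12 of 14 above 0, median 0.24, with Zmat3 at 0.84 and Mdm2 at 0.67), inflammatory cytokines (0.25, with Ptgs2 at 0.76 and Tnfaip3 at 0.73), ribosome biogenesis (0.22) and serum and immediate early genes (0.13, with Myc at 0.69). Endoplasmic reticulum stress genes had a median of -0.12 and the Notch and inhibitor list -0.17, both just below their random range. The markers of 4 other cell types stood higher, with medians of 0.30 for chondrocyte, 0.28 for fibroblast, 0.27 for adipocyte and 0.25 for smooth muscle and myofibroblast, all above their random ranges. Setting dim values to a floor at the 25th percentile of each array took the first 3 of these, and the inflammatory list, back inside. Many of their members read low on every array, such as Adipoq at 4.81 and 5.36 in control and siMUNC proliferating cells. The long noncoding RNA H19 was 1.99-fold lower.

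The comparison of the siRNAs in differentiating cells is the one the series is named for. Muscle genes were lower with siMUNC. Casq1, the calsequestrin of fast muscle, was 8.97-fold lower, Trdn (triadin, of the calcium release complex) 6.74-fold, Smpx 6.49-fold, the stretch-responsive Ankrd2 6.31-fold, Myoz2 6.28-fold and the muscle LIM protein Csrp3 5.69-fold. Of the regulators, Mef2c was 4.13-fold lower, Myog 3.13-fold, Smyd1 2.16-fold, Tead4 2.10-fold and Myod1 2.06-fold. Cell cycle genes were higher, among them Ccnd1, which encodes cyclin D1 (3.40-fold), Ccne2 (2.87-fold), Bub1 (2.63-fold) and Mki67 (2.29-fold).

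No member of the thick filament, thin filament and Z-disc, excitation-contraction coupling or neuromuscular junction lists was above 0. Past 2-fold lower were 6 of 8 thick filament genes, the dim Myl2 among them (median -1.36; Mybpc1 -2.37, Myom1 -2.33, Mybpc2 -2.05), 12 of 20 thin filament and Z-disc genes (-1.33; Nrap -2.35, Actn2 -2.29, Tnni2 -1.87) and 10 of 19 excitation-contraction coupling genes (-1.16; Cacna1s -2.31, Hrc -1.82, Jph1 -1.82). The same held for 7 of 14 muscle energy metabolism genes (-0.97; Pygm -2.27, Pgam2 -1.94, Ckm -1.63), 5 of 11 myogenic transcription factors (-0.69) and 1 of 9 neuromuscular junction genes (-0.52; Chrnd -1.21). Some abundant muscle genes differed by less than 2-fold, such as Acta1 (-0.69), Mylpf (-0.84), Myl1 (-0.83), Atp2a1 (-0.87) and Mymk (-0.78). The fusion list had a median of -0.01, inside its random range, with Dysf, a membrane repair protein, past 2-fold lower (-1.61). Within the transcription factor list Myf5 (0.62) and Myf6 (0.21) were higher, Myf6 from dim values (8.24 in control and 8.46 in siMUNC cells).

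Past 2-fold higher were 17 of 20 mitotic genes (median 1.13; Bub1 1.39, Aurka 1.36, Ttk 1.33, Cenpe 1.32) and 5 of 25 DNA replication genes (0.79; Ccne2 1.52, Mcm3 1.17, Ccne1 1.09). All 45 were above 0. Cell cycle exit genes had a median of -0.13, inside their random range, with Cdkn1c, the p57 inhibitor, past 2-fold lower (-1.13) and Cdkn1a at -0.12. Inflammatory cytokines were higher as a list (0.44; Ccl2 1.56, Ptgs2 1.28), as were p53 targets (0.42; Perp 1.71, Zmat3 1.19, Trp53inp1 1.09), interferon response genes (0.24, none past 2-fold; Rsad2 0.93, Ifit1 0.91) and serum and immediate early genes (0.22; Myc 1.05, Dusp6 0.98). Oxidative phosphorylation genes were lower in 12 of 14 cases, by small amounts (-0.24; Cox4i1 -0.48). The remaining lists lay inside their random ranges: extracellular matrix (0.05, although Lum was at -3.55 and Tnc was 2.46-fold higher), the Notch and inhibitor list (0.04, with Id3 at -1.41), cholesterol synthesis (0.04), endoplasmic reticulum stress (-0.07), ribosome biogenesis (0.13), housekeeping (0.21) and long noncoding RNAs (0.00).

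Of 7635 expressed genes 152 were past 2-fold higher and 175 past 2-fold lower with siMUNC, and 3 and 26 were past 4-fold. Several of the lowest were secreted or enzyme genes rather than contractile ones: Lbp, the lipopolysaccharide-binding protein (14.2-fold), Serpina6, the corticosteroid-binding globulin (12.9-fold), the matrix proteoglycan Lum (11.7-fold), Cyp2f2 (8.72-fold) and Dpep1 (-2.46 on the log2 scale). The 12 highest expressed genes were the tight junction gene Cldn1 (9.73-fold), Slc19a2 (4.53-fold), Cd200r2 (4.04-fold), Mybl1 (3.97-fold), Mcpt8 (3.90-fold), Ctxn1 (3.53-fold), Clca3b (3.45-fold), Sfrp2, a secreted Wnt modulator (3.41-fold), Ccnd1, Perp (3.27-fold), Il33 (3.12-fold) and Havcr2 (3.09-fold). Several of these folds rest on a dim value, such as 6.09 for Cldn1 in control and 6.84 for Lum in siMUNC differentiating cells. Their size and order thus depend on the background. Of the other marker lists, smooth muscle and myofibroblast stood just below its random range (-0.16; Mylk -1.41, and the dim Lmod1 -1.03) and fibroblast just above (0.21), and quantile normalization took both back inside. Osteoblast (-0.05, with Phex at -2.08), adipocyte (0.00), chondrocyte (0.02), macrophage (0.01) and reserve and satellite cell markers (0.09, with Met at 1.12 and Cd34 at 1.08) lay inside.

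**Figure D3:**
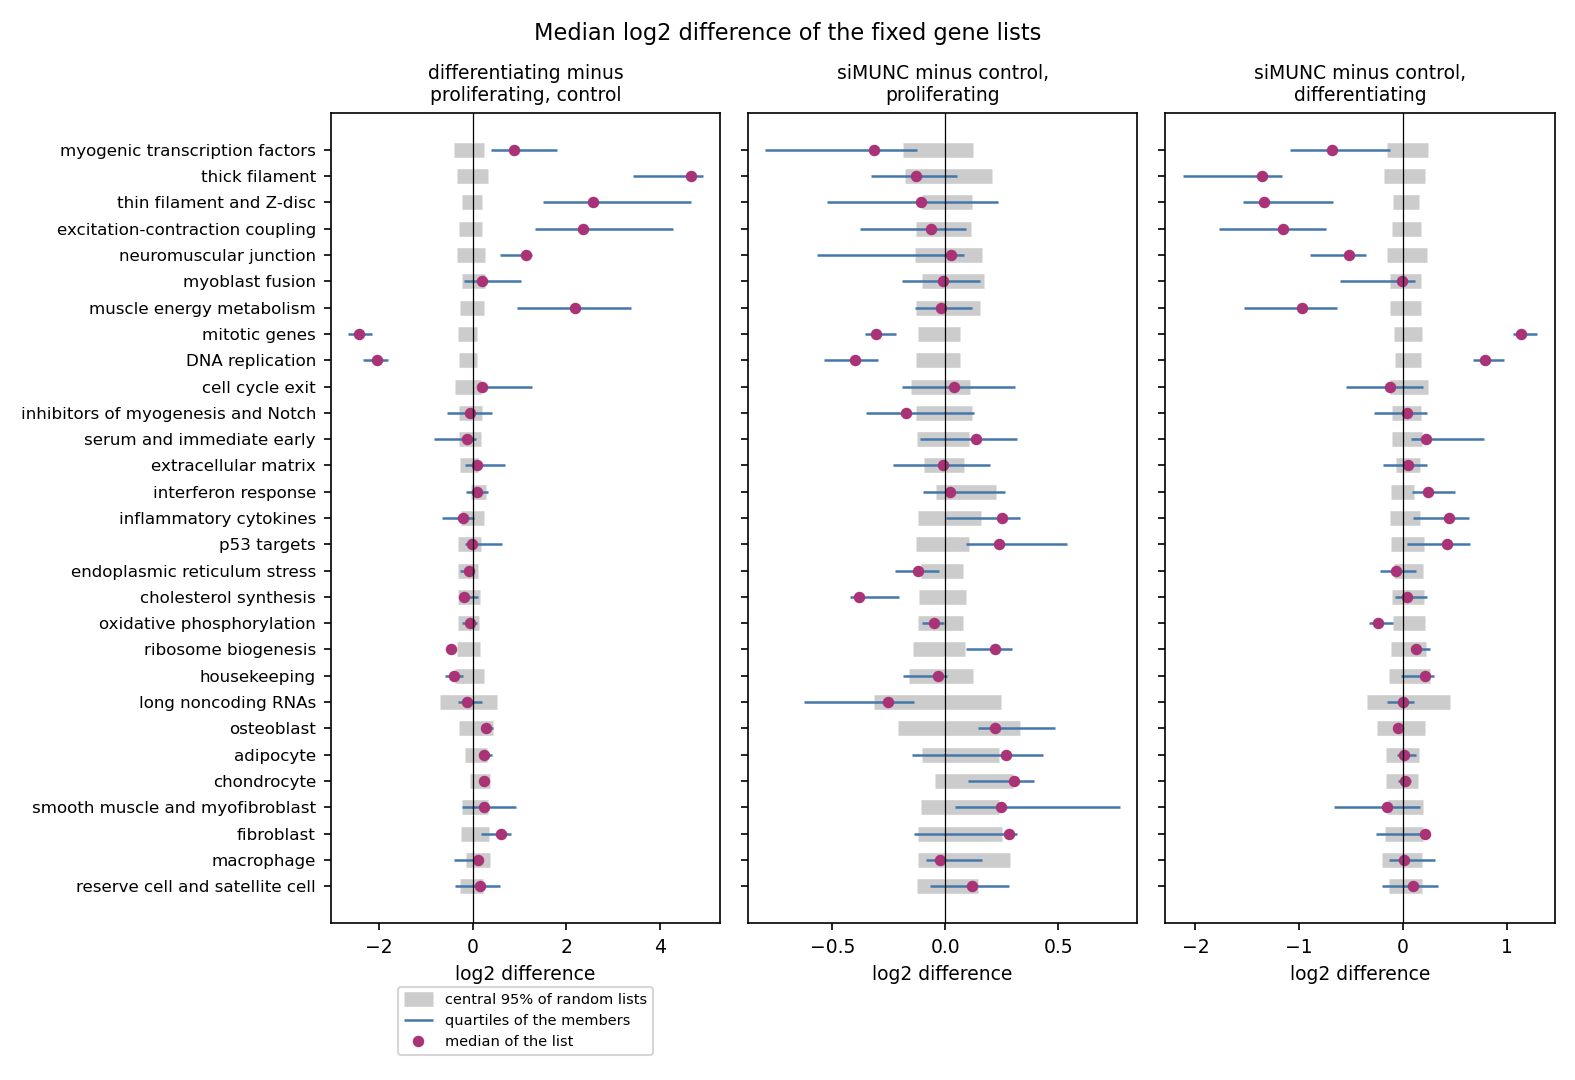
Median log2 difference of each of the 29 fixed lists (points), with the quartiles of its members (lines) and the central 95% of 10000 random lists matched on expression (grey bars), in 3 comparisons whose horizontal axes have different ranges. The muscle lists lie to the right in the first panel and to the left in the third, such as thick filament at 4.67 and -1.36, and the mitotic list lies at -2.42 and 1.13.

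Genes were next picked by the mean of both differentiation differences, a choice that shares no array noise with the knockdown difference if the arrays are equally noisy. Of 322 genes with a mean at least 2-fold higher on differentiation, 281 (87.3%) read lower with siMUNC in differentiating cells, 136 of them past 2-fold (median -0.84, quartiles -1.45 and -0.35). In proliferating cells their median was -0.09, and -0.03 with the arrays centred. Of 310 genes at least 2-fold lower on differentiation, 300 read higher with siMUNC in differentiating cells, 121 past 2-fold (median 0.86, quartiles 0.56 and 1.13), and in proliferating cells their median was -0.34. Each median lay outside the range of matched random lists.

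The last comparison is the difference between the differentiation effects in siMUNC and control cells, taken over all 4 arrays. The widest shortfalls were in Serpina6 (log2 differences on differentiation of 4.78 in control and 1.08 in siMUNC cells), Casq1 (4.96 and 1.81), Lum (4.87 and 1.72), the small heat shock protein Hspb7 (4.18 and 1.09), Cyp2f2 (3.46 and 0.47) and Lbp (3.08 and 0.11). Several of these were dim in proliferating cells, such as Serpina6 (5.25 in control and 5.26 in siMUNC cells), Lum (5.52 and 5.13) and Casq1 (5.77 and 5.76), so the size and order of the shortfalls depend on the background. Myl1 and Mymk had no shortfall (0.21 and 0.23). On the other side, Cldn1 was 6.08-fold higher on differentiation in siMUNC cells and 1.12-fold lower in control cells, and Sfrp2 was 9.86-fold and 2.02-fold higher. Tmprss11f, Ercc6l and Ccdc73 were lower on differentiation in both, by less with siMUNC (differences of 2.45, 2.22 and 2.11).

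Past 2-fold below 0 in this difference were 6 of 8 thick filament genes (median -1.31), 9 of 20 thin filament and Z-disc genes (-0.95), 10 of 19 excitation-contraction coupling genes (-1.05), 8 of 14 muscle energy metabolism genes (-1.11), 1 of 11 myogenic transcription factors (Mef2c, -1.05; list median -0.53) and 0 of 9 neuromuscular junction genes (-0.39). Past 2-fold above 0 were 19 of 20 mitotic genes (1.45) and 21 of 25 DNA replication genes (1.23). Cholesterol synthesis genes were above 0 in 15 of 15 cases (0.44), with Lss (0.64), Msmo1 (0.61), Insig1 (0.60) and Cyp51 (0.60) farthest. Smooth muscle and myofibroblast markers were below 0 in 7 of 8 cases (-0.60), with Lmod1 (-2.11, but between 5.83 and 7.60 on all 4 arrays and thus dim) and Mylk (-1.29) past 2-fold. Over 7968 expressed genes 236 were past 2-fold above 0 and 142 past 2-fold below. This difference shares arrays with each of the other comparisons, so their counts are not separate evidence.

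The knockdown differences in proliferating and differentiating cells share no array. Of 7231 genes expressed in both, 3 were past 2-fold higher in both states (Il33, Slc19a2 and Trp53inp1; 0.14 for independent lists) and 6 past 2-fold lower in both (Ano5, Apobec2, C1qtnf3, Cxcl13, Islr and Kcnj2; 0.13). Ano5, Apobec2 and Islr were singled out after their values were seen. Of the 175 genes past 2-fold lower in differentiating cells 52 were among these 7231, and of the 152 past 2-fold higher 145. The others were dim on both proliferating arrays and are left out of these overlaps. Across the 7231 genes the differences had a Pearson correlation of 0.347 (Spearman 0.352).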

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

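The tests of normalization, of intensity-dependent bias and of an effect common to both states were chosen only after the results were seen; the other tests were set beforehand. For normalization, other scalings had been set beforehand, but the arrays were already so alike that these could not have moved the medians far, and they are not used as a test here. No difference between knockdown effects below was tested, since each group has 1 array.

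In 15 expressed genes the knockdown difference went one way in proliferating and the other way in differentiating cells, past 1.5-fold in each. Independent lists would give 13.5, so the number of such genes is no result in itself. Fst, the activin-binding protein follistatin, was 1.81-fold higher with siMUNC in proliferating cells and 2.00-fold lower in differentiating cells, a gap of -1.86 on the log2 scale. The 5 next by size were cell cycle genes that were lower before and higher after the change of medium: Mki67 (gap 1.83), Nek2 (1.80), Mastl (1.76), Sgo1 (1.76) and Uhrf1 (1.74), a DNA methylation cofactor. The lists with medians outside their random ranges on opposite sides of 0 in the 2 states were mitotic genes (gap 1.44), DNA replication genes (1.19) and smooth muscle and myofibroblast markers (-0.41), the last taken back inside by quantile normalization. Other lists differed between the states without being outside on opposite sides, such as thick filament with medians of -0.13 and -1.36. Among clusters left out of the comparisons, 26 with no gene in the annotation table and 15 with several genes were past 2-fold between the siRNAs in differentiating cells.

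For muscle genes lower and cell cycle genes higher in differentiating siMUNC cells, normalization between arrays, which moves genes of equal level alike, is argued against: the joined medians of 61 muscle genes (-1.20) and 45 cell cycle genes (0.99) lay on opposite sides of random lists matched on the level in these 2 arrays, each beyond their central 95% by at least 0.868. The same lists had already been placed outside random lists matched on mean expression in this comparison. The distances of the joined medians largely restate that and are not independent support. Intervals in this paragraph and the next come from resampling genes, which are not replicates, so they hold no spread between cultures. Undifferentiated siMUNC cells mixed in at a single proportion cannot be told apart: muscle genes called for a proportion of 0.712 (interval 0.649 to 0.762, 50 genes) and cell cycle genes for 0.352 (0.319 to 0.382, 42 genes), a gap of 0.360 that met the bound set beforehand. That bound was wrong by design, since it gave such cells the profile of proliferating cells in growth medium, and no array holds undifferentiated cells in 2% horse serum, which may cycle less. A difference between the cultures other than the siRNA, such as density or the time of the medium change, cannot be told apart from the knockdown with 1 array per group. The biological candidate, loss of MUNC, therefore stays open beside both, and the knockdown itself was not measured here.

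Genes higher on differentiation were not reduced alike. Of 94 with a mean effect of at least 2 on the log2 scale, 69 were past 2-fold lower with siMUNC (median -1.56) and 11 were within 1.5-fold, among them Dpt (0.25), Spry1 (0.21) and Cd36 (0.11), while Casq1 stood at -3.16. Low signal cannot be told apart either: the 31 dimmest differed from the rest by -0.161 (interval -0.437 to 0.674). That interval allows a larger or a smaller loss in the dimmer genes. The difference and its interval met the bound set beforehand for arguing against low signal. That bound could not decide it, since these 31 had a median level of 10.0 in control differentiating cells. As a group they were thus not low in signal there. Saturation of bright genes may contribute and cannot be told apart: the 31 brightest were nearer 0 by 0.385, with an interval from -0.00236 to 0.661 that leaves it undecided. No biological explanation of the unequal loss was tested.

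Replication and mitotic genes, joined into 1 list, were lower with siMUNC in proliferating cells (median -0.33, 44 of 45 below 0) and higher in differentiating cells (0.99, 45 of 45 above 0). A bias that depends on intensity is argued against, because the joined median lay beyond the central 95% of matched random lists by at least 0.237 in both states. Normalization between arrays is argued against in the same way, by a distance of at least 0.247 in both states from lists matched on the 2 arrays compared. The replication and mitotic lists were flagged by the same kind of placing, so these distances largely restate it and are not independent support. A difference in density or growth between the cultures cannot be told apart from the siRNA with 1 array per group, in either state.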

How the results depend on the processing

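No result turned its direction past the threshold under any of the 11 alternatives, and no gene called in one direction was called in the other. This outcome was largely fixed in advance. Filters and thresholds leave the sign of a gene's difference as it is, and the arrays were already too alike for other scalings to move much. Pairing the arrays across the states or the siRNAs was not done, since it would count the difference of effects as noise. Leaving out an array removes every comparison that uses it, because each group has 1 array. Between quantile normalization, centring and cyclic loess, the median of genes higher on differentiation stayed between -0.86 and -0.79 in differentiating siMUNC cells and that of genes lower on differentiation between 0.82 and 0.87. With sets picked at 1.5-fold these medians were -0.52 and 0.51, and at 3-fold -1.39 and 1.11, by construction. Of 39 counts that moved by over 1.5 times, 20 come from the thresholds of 1.5-fold and 3-fold, and others from the threshold of 3 running SDs. At 1.5-fold, genes higher and lower numbered 826 and 1210 (differentiation, control), 497 and 453 (differentiation, siMUNC), 72 and 200 (knockdown, proliferating), 512 and 468 (knockdown, differentiating) and 678 and 340 (difference of effects). At 3-fold they numbered 207 and 254, 89 and 10, 0 and 1, 14 and 66, and 57 and 57, in the same order. A filter at the 75th percentile, which leaves fewer genes, gave 241 and 305, 110 and 48, 6 lower for the knockdown in proliferating cells, 65 and 109, and 151 and 77. With no filter on dim genes there were 35 and 52 for the knockdown in proliferating cells and 252 lower for the difference of effects, from the added dim genes. An offset of 50 gave 13 lower among expressed genes in proliferating cells, since it shrinks differences the more the lower the values compared. At 3 running SDs, which sets the threshold by the spread at each intensity, there were 338 lower (differentiation, control), 178 lower (differentiation, siMUNC), 74 and 165 (knockdown, proliferating) and 245 and 264 (knockdown, differentiating). The share of higher calls for the knockdown in proliferating cells was 23.3% as deposited and 33.3% after quantile normalization or centring, and centring shifted the median of all genes by at most -0.0905. Counted over all alternatives, calls of single genes were lost 158 times and gained 265 times, and list medians left their place outside the random range 19 times and gained one 20 times. Without scanner files, the signal over background was not analysed here.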

Other observations

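The test in the second paragraph was chosen after the result was seen. Several differences were present with siMUNC in both states. Among p53 targets, Trp53inp1 was higher by 1.19 in proliferating and 1.09 in differentiating cells, Zmat3 by 0.84 and 1.19, Mdm2 by 0.67 and 0.60, Plk2 by 0.54 and 0.51 and Aen by 0.54 and 0.46. Cdkn1a, another target, was higher in proliferating cells (0.45) and not in differentiating cells (-0.12), and Sesn1 was lower in both (-0.37 and -0.59). Among inflammatory genes, Ptgs2 (0.76 and 1.28) and Tnfaip3 (0.73 and 0.63) were higher in both, whereas Ccl2 went from 0.32 to 1.56. Cxcl5 (-0.50 and -0.82) and Cx3cl1 (-0.15 and -0.47) were lower in both, and 12 of the 15 members were above 0 in each state.

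A hypothesis is that part of the siRNA effect does not depend on the state of the cells. Of 7231 genes expressed in both states, 89 were past 1.5-fold in the same direction in both, against 10.9 for independent lists, a ratio of 8.17, and 15 in opposite directions, against 13.5. These 7231 hold 283 of the 468 genes past 1.5-fold lower in differentiating cells and 497 of the 512 past 1.5-fold higher. The others were dim on both proliferating arrays and are left out. The ratio thus covers only part of the differences in differentiating cells. The 2 knockdown comparisons share no array. The same data had prompted the hypothesis, through overlaps seen at 2-fold, so this ratio describes it and leaves it open. The shared part may come from MUNC itself or from other effects of the siRNA duplex, which the design, with 1 siRNA label per group, does not separate.

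In control cells the differentiating array stood apart: 156 genes read at least 2-fold above all 3 other arrays and 142 at least 2-fold below. On the differentiating siMUNC array 8 genes read above all others (Ccn3, Cd200r2, Cldn1, Il33, Perp, Rerg, Sfrp2 and Vldlr) and 1 below (Id3). These genes were singled out after their values were seen. In proliferating siMUNC cells 1 gene read above all others (Tagln) and 14 below, Myl1 and Mymk among them.

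Of all genes expressed in both differentiation comparisons, 1 was past 1.5-fold in opposite directions: Adgrg1, an adhesion receptor, read 0.71 on differentiation in control and -0.71 in siMUNC cells. It was singled out after its values were seen.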
